A study of Homo sapiens with 2 samples.

How the data were processed

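The samples were 2 RNA pools from extracellular vesicles, small membrane-bound particles that cells release. One pool came from primary lung fibroblasts of patients with idiopathic pulmonary fibrosis (IPF) and the other from lung fibroblasts of individuals without IPF. Per the labels, fibroblasts grown with fetal bovine serum were moved to a serum-free medium, and that medium was collected. Debris was cleared by a 10 min spin at 2000 x g and a filter, and vesicles were pelleted at 35000 rpm for 70 min, washed and pelleted again. Column-purified total RNA from 6 vesicle preparations per group was pooled, and 20 ng of each pool was labelled with Cy3 and hybridised to 1 Agilent human miRNA array. The design therefore held 2 arrays in 2 groups, 1 per group. Both arrays were on the same slide and in the same scan, per the file headers, so no slide or scan separated the groups.

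Per the file headers, the authors' scanner files were written by Agilent Feature Extraction 11.5.1.1, and each held 53144 spots, of which 50980 were spots of 5893 probes for 2549 human miRNAs. The deposited spot intensity was background-subtracted by Feature Extraction with spatial detrending and was not normalized between arrays, per the file headers. The files also gave raw spot and local background intensity, a total gene signal per miRNA, and flags for outliers, saturation and signal well above background. Probe positions in the files were on hg19. Host genes were looked up by precursor name in a RefSeq gene table of GRCh38, of which only gene names and neighbourhood were used. The authors' deposited value table held log2 values. Set against the scanner files, all 2549 rows lay within 0.001 of log2 of the total gene signal minus 1 constant per array, 6.21 for IPF and 5.71 for non-IPF. The column medians were −9.53 and −9.03, because 1922 and 1979 miRNAs that were not detected stood at a total gene signal of 0.1. What the constants are is not stated in the sources used here, so the centring of that table remained unknown. Its direction and log base were settled by this match.

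For each array, the background-subtracted intensity was averaged over the spots of a probe after outlier spots were removed (1398 spots, 2.74%, on the IPF array and 1461, 2.87%, on the non-IPF array). No spot was saturated. A probe was called detected where at least 0.5 of its remaining spots were well above background. Signals were divided by the 75th percentile over the 806 probes detected on both arrays (237.9 for IPF and 165.9 for non-IPF), floored at the lowest detected signal of that array, and taken to log2. This scaling sets the bulk of the miRNAs equal between the pools, so a shift shared by most miRNAs does not appear in the ratios. A miRNA was represented by its probe with the highest mean signal. For 345 miRNAs more than 1 probe was detected, with a median range of 0.07 in log2 ratio between probes. The range exceeded 1 for 1 miRNA, and the probes differed in sign for 50. The error given with a log2 ratio is the SD over the spots of the probe, combined over both arrays. It is technical only and holds nothing of the spread between people, cultures or pools. With 1 array per group no test between groups was possible, no p-value was calculated, and a miRNA was counted as different where its signals differed at least 2-fold (log2 ratio of 1). A miRNA detected on 1 array only has a bound: its signal over the higher of the lowest detected signal on the other array and its own signal there.

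A total of 16 miRNA lists, the rule for naming miRNAs and most alternatives were set before the data were examined. Named miRNAs were those with at least the median mean signal that were among the 10 highest or 10 lowest at least 2-fold different, the 5 brightest on each array, up to 5 per array detected there only with a bound of at least 2-fold, miR-23b-3p and miR-494-3p, and up to 4 of the brightest detected members of each list. This gave 44 miRNAs, and any other miRNA was named after its value was seen. The median log2 ratio of a list with at least 3 members detected on both arrays was placed among 10000 random lists of the same size drawn from miRNAs in the same of 10 classes of mean signal. The percentile describes these 2 arrays and is not a test. List members were chosen from general knowledge of the literature, and several lists overlap.

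Alternatives were the percentile over all probes, the median of detected probes, the percentile without GC-rich miRNAs, quantile normalization, no scaling, the mean of all probes, total gene signal, the gene detection flag, outlier spots kept, the upper part of mean signal, detection on every spot, the deposited value table, and normexp background correction (offset 50) with limma 3.58.1 in R 4.3.3. A fold threshold of 1.5 and random lists matched on probe GC content were added after the data were seen. The GC-matched lists were first drawn with the list's own members among the miRNAs to draw from, and then, after those values were seen, from other miRNAs only. The second draw also let a miRNA enter a random list more than once, so a change between the draws may come from either step. Both draws are given where they differ in reading. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. The calculation was tested on simulated data for 2549 miRNAs in the IPF against non-IPF comparison, with 200 miRNAs given known folds. Of those set to differ 3-fold, 95 were detected on both simulated arrays and 95 were called. Of those set to differ 1.5-fold, 99 were detected and 0 were called, and 0 of 313 detected miRNAs with no set difference were called. The simulated arrays differed only by the set folds, spot noise and an overall brightness. These calls therefore check the calculation and give no rate of false calls between pools. Of 200 random lists, 8 fell outside the central 95% of their matched random lists, and all 50 lists built to hold a 1.5-fold shift fell above it. The number of arrays limits the precision of every comparison.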

Results

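The miRNA content of extracellular vesicles from primary lung fibroblasts was measured to ask how vesicles released by fibroblasts of patients with idiopathic pulmonary fibrosis (IPF), a progressive scarring disease of the lung, differ from those of individuals without IPF. Each group was represented by 1 array, hybridised with RNA pooled from 6 vesicle preparations. The arrays carried probes for 2549 human miRNAs, short RNAs that repress messenger RNAs. With 1 pool per group there was no replicate check, and every value with ± gives the SD over spots of the array, which is technical only. Ratios are log2 of IPF over non-IPF signal after each array was scaled to its 75th percentile of detected probes.

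The vesicle pools carried similar sets of miRNAs. In the IPF pool 501 miRNAs were detected (19.7% of those on the array) and in the non-IPF pool 446 (17.5%), and 438 were detected in both. The probes with the highest signal on both arrays were those of miR-7975, miR-7977, miR-5100, miR-4459 and miR-4286. All of these except miR-4459 were listed beforehand as possibly fragments of other small RNAs annotated as miRNAs. miR-4459 was listed among GC-rich miRNAs that are often bright on this kind of array. The brightest signals may therefore not come from miRNAs. The unscaled signal of miR-7975 was 131073 in IPF and 89587 in non-IPF, and that of miR-7977 was 102904 and 68024. Together these made up 53.3% of the summed signal of detected miRNAs in IPF and 52.1% in non-IPF, and the 10 brightest miRNAs held 73.9% and 72.0%. After scaling, miR-7975 had a log2 ratio of 0.03 ± 0.06, miR-7977 0.08 ± 0.06, miR-5100 0.16 ± 0.02, miR-4459 0.07 ± 0.11 and miR-4286 0.32 ± 0.04. Quantile normalization, which gives the brightest miRNAs of both arrays the same values, set these to 0. Median scaling, which shifted every ratio by −0.06, turned miR-7975 to −0.04.

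Scaled signals of the pools were close, and no miRNA was at least 2-fold higher in IPF vesicles, while 8 were at least 2-fold lower. Across the 438 shared miRNAs the Pearson correlation of log2 signals was 0.988, a value across miRNAs of 1 pair of arrays, which are not independent replicates. The remaining 430 (98.2%) lay within 2-fold. The lowest ratio was that of miR-1290 (−1.39 ± 0.05), followed among the brighter miRNAs by miR-1246 (−1.31 ± 0.09), miR-4455 (−1.27 ± 0.16), miR-574-5p (−1.22 ± 0.11) and miR-762 (−1.04 ± 0.08). In miR-1246 the unscaled signal was 2763 in IPF and 4764 in non-IPF. The sequences annotated as miR-1246 and miR-1290 have been described as related to U2 small nuclear RNA. The precursor of miR-574-5p lies within FAM114A1, that of miR-762 within BCL7C and that of miR-1290 within ALDH4A1 in the GRCh38 gene table. The other 3, named after their values were seen, were dim: miR-32-3p (−1.31 ± 0.19; probe match on chromosome 9 of hg19, 111808556 to 111808576), miR-595 (−1.21 ± 0.26) and miR-3149 (−1.21 ± 0.30). In all 8 the scaled spots of the 2 arrays did not overlap. This largely follows from choosing them by their ratio, given spot SDs of 0.30 or less, and is no separate support. The count depended on scaling and background correction. Without scaling, 8 miRNAs were at least 2-fold higher and 0 at least 2-fold lower in IPF, because the unscaled signal was higher in IPF for 415 of the 438 (median 1.45-fold). The 8 miRNAs named here then stood between −0.88 and −0.52. Total gene signals gave 11 higher and 14 lower, and the deposited value table gave 13 and 14. With normexp background correction 0 were higher and 2 were lower. The 8 miRNAs named here then stood between −1.20 and −0.60, all within the 10 lowest ratios.

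**Figure D1:**
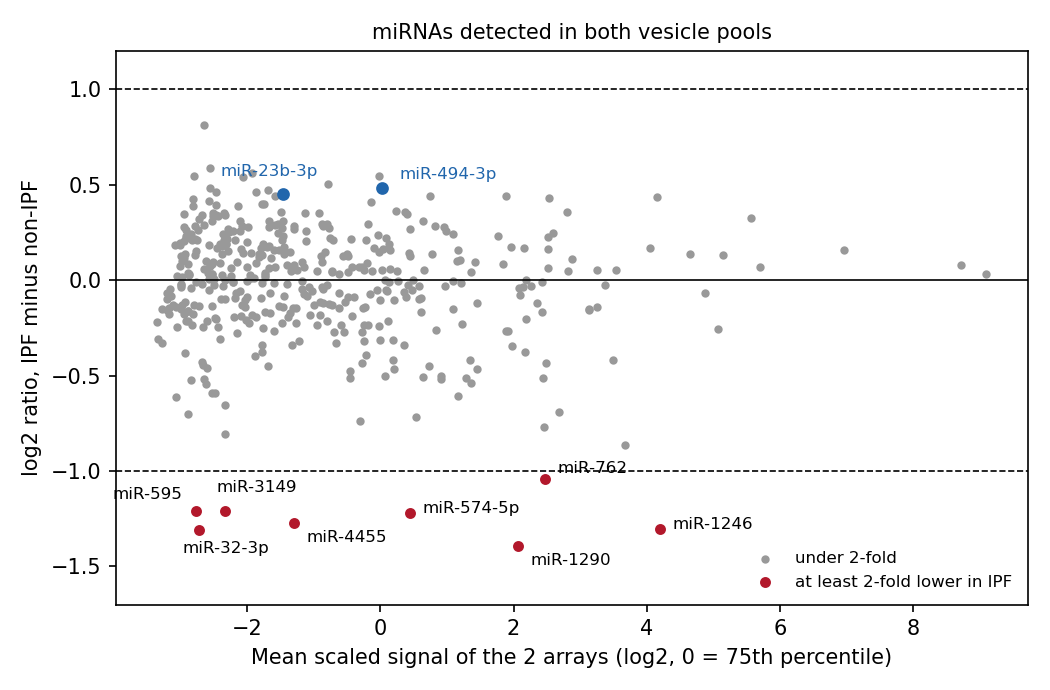
Each point is 1 of the 438 miRNAs detected in both pools, with the mean scaled log2 signal of the 2 arrays on the x axis and the log2 ratio of IPF over non-IPF on the y axis; dashed lines mark 2-fold. The 8 red points lie between −1.39 and −1.04, and no point lies above the upper dashed line.

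Of the miRNAs detected in 1 pool only, 63 were detected in IPF and 8 in non-IPF vesicles. Detection was called before scaling, with lowest detected signals of 19.3 in IPF and 17.2 in non-IPF, while most miRNAs were brighter on the IPF array. The excess on that array, here and within the lists below, is therefore not read as a difference between the pools. None of the 63 had a bound of 2-fold, the highest being at least 1.57-fold. Of the 8, only miR-4674 passed 2-fold, at least 2.37-fold higher in non-IPF, with an unscaled signal of 31.9 against −0.96 in IPF, where it was not well above background. Without scaling, 2 of the 63 had a bound of at least 2-fold (the highest at least 2.25-fold) and miR-4674 was at least 1.65-fold higher in non-IPF. The bound of miR-4674 was also under 2-fold with normexp (1.48) and with the mean of all probes (1.74). Total gene signals, which detect more dim miRNAs, put 25 of 76 found in IPF only and 18 of 19 found in non-IPF only at 2-fold or more, and the deposited values gave 27 and 18.

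The study is recalled to have followed up miR-23b-3p and miR-494-3p. How it chose them is not given in the sources used here, so their direction is not taken as independent evidence. Both had higher scaled signal in IPF vesicles and both were under 2-fold. The ratio of miR-23b-3p was 0.45 ± 0.15, with unscaled signals of 101 and 51.5, and it was 13th from the highest of the 438. Its probe matched chromosome 9 of hg19 at 97847552 to 97847567, and its precursor lies within the gene AOPEP in the GRCh38 table. The ratio of miR-494-3p was 0.48 ± 0.09, with unscaled signals of 287 and 143, and it was 8th from the highest. Its probe matched chromosome 14 of hg19 at 101496027 to 101496039, in the imprinted miRNA cluster at 14q32. Without scaling the ratios were 0.97 and 1.003. With normexp background correction, which lowered the median of all miRNAs by 0.13, miR-23b-3p stood at 0.13 and at rank 52, and miR-494-3p at 0.36 and rank 8. By total gene signal, with 551 miRNAs detected in both pools, the ratios were 0.43 and 0.43 and the ranks 57 and 59. With the gene detection flag, which also put 551 in both pools, the ranks were 15 and 9, so the larger number alone does not give the lower ranks. With the mean of all probes the ranks were 13 and 17.

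miRNAs tied to fibrosis that were detected in both pools were all within 2-fold. Of 15 miRNAs listed beforehand as profibrotic in lung, 8 were detected in both pools, 0 of them 2-fold different, with 6 ratios above 0. The label came from general knowledge of the literature and may not hold for every member. The median of the 8 was 0.22, at percentile 98.4 of random lists matched on signal, and was 0.048 with normexp. Matched on probe GC content as well, the list was at percentile 95.3, inside the central 95%. Among the 8, miR-145-5p, a miRNA of smooth muscle cells and myofibroblasts (chromosome 5, 148810230 to 148810246, within CARMN), was at 0.41 ± 0.11, miR-34a-5p, a target of p53, at 0.35 ± 0.21, and miR-199a-5p at 0.27 ± 0.09. The widely studied miR-21-5p (chromosome 17, 57918637 to 57918655, within VMP1) was at 0.11 ± 0.05. Of 25 antifibrotic miRNAs, 18 were detected in both pools and 2 in IPF only. Of the 18, 12 had ratios above 0 and 0 were 2-fold different. The median of 0.09 lay at percentile 87.5 and turned to −0.03 with normexp, which shifted the median of all miRNAs by −0.13. In this list miR-29a-3p, which targets collagen messenger RNAs, was at 0.11 ± 0.12, and the highest ratio, named after its value was seen, was that of miR-30a-5p at 0.56 ± 0.22. The let-7 family, 8 of 9 detected, had a median of −0.04 (percentile 34.7), with let-7a-5p at −0.03 ± 0.21, let-7b-5p at −0.09 ± 0.12, let-7c-5p at −0.14 ± 0.11 and let-7f-5p at −0.05 ± 0.17. The probes of these let-7 miRNAs are nearly the same in sequence, so they may not be separate measurements. All 8 are also among the 18 antifibrotic miRNAs, and 2 of them had ratios above 0. Every other antifibrotic miRNA detected in both pools had a ratio above 0. The let-7 median was 0.05 when GC-rich miRNAs were left out of the scaling, which shifted every ratio by 0.09 and so tells nothing of let-7 itself. Leaving scaling out raised the median of all miRNAs by 0.52 and put all 12 list medians above 0.

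miRNAs typical of fibroblasts were well represented in both pools. Of 25 fibroblast-abundant miRNAs 21 were detected in both pools and 1 in IPF only. Of the 21, 17 had ratios above 0 and 0 were 2-fold different, and the median was 0.11 (percentile 95.1). miR-125b-5p was at 0.23 ± 0.12. The clusters that encode miR-23, miR-27 and miR-24 had 5 of 11 members detected, all with ratios above 0, and a median of 0.29 at percentile 99.1, which was 0.15 with normexp. Their values were 0.10 ± 0.11 for miR-23a-3p, 0.23 ± 0.13 for miR-27a-3p, 0.29 ± 0.16 for miR-27b-3p and 0.31 ± 0.09 for miR-24-3p. The highest was miR-23b-3p at 0.45 ± 0.15. All 5 belong to the fibroblast list as well. Because miR-23b-3p is recalled as followed up by the study, these lists are not taken as independent evidence. The same holds for the 14q32 and senescence lists, which hold miR-494-3p. The probes of miR-23a-3p and miR-23b-3p are nearly the same in sequence, as are those of miR-27a-3p and miR-27b-3p. These members may therefore not be separate measurements. Matched on probe GC content as well as signal, the clusters were at percentile 95.5. The 14q32 cluster had 6 of 63 members detected in both pools and 4 in IPF only (miR-127-3p, miR-370-3p, miR-377-3p and miR-382-5p, named after their values were seen). The median of the 6 was 0.12 (percentile 71.0), which was −0.12 with normexp. Its members went both ways, with miR-376a-3p at 0.25 ± 0.22, miR-134-5p at −0.01 ± 0.17 and miR-1185-1-3p at −0.40 ± 0.27. The miR-17/92 cluster and its paralogs, which promote proliferation, had 7 of 14 members detected in both pools, 1 in IPF only, and a median of −0.01 (percentile 16.4). It was 0.08 without GC-rich miRNAs in the scaling, a setting that shifted every ratio by 0.09. There miR-92a-3p was at −0.17 ± 0.21, miR-19b-3p at −0.01 ± 0.15, miR-106b-5p at −0.01 ± 0.30 and miR-25-3p at 0.07 ± 0.20. Of the cluster that holds miR-424-5p, with 7 members on the array, only miR-424-5p was detected, at 0.40 ± 0.23. Of 19 senescence-associated miRNAs 13 were detected, 8 with ratios above 0, and their median was 0.11 (percentile 90.2), with miR-22-3p at 0.28 ± 0.08 and miR-16-5p at −0.31 ± 0.11.

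**Figure D2:**
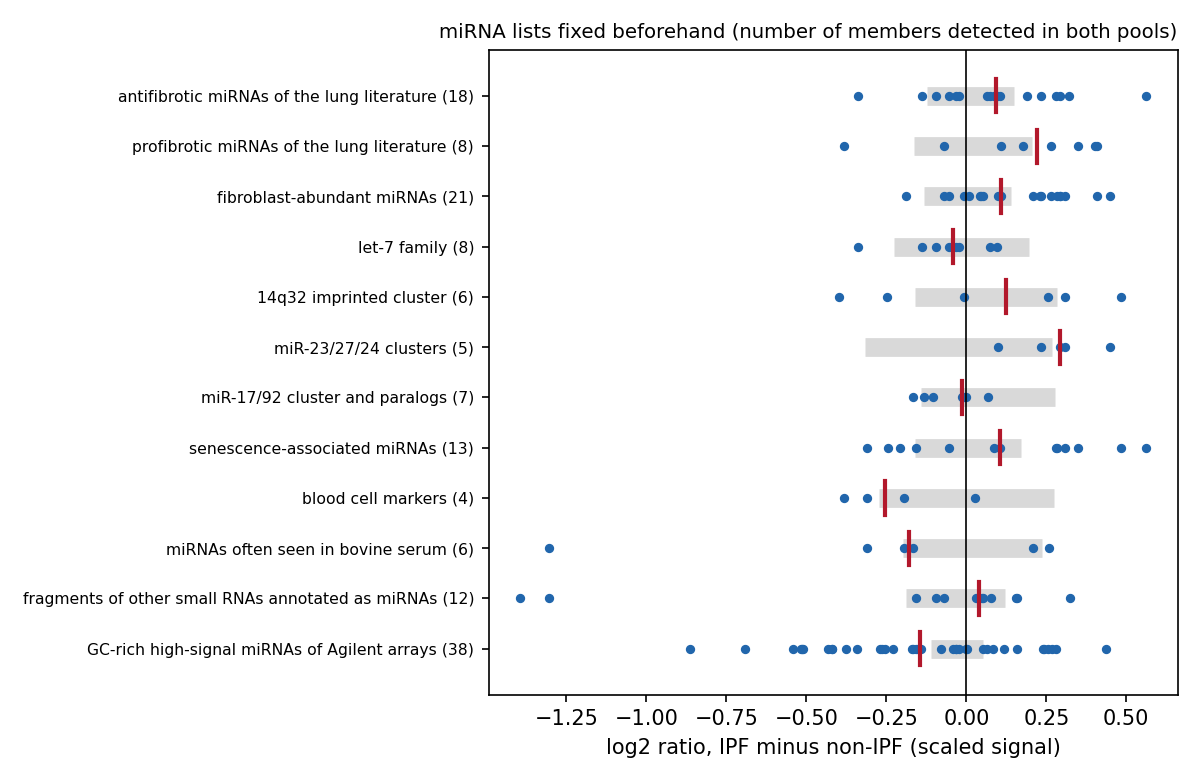
Points are the log2 ratios (IPF over non-IPF, scaled signal, x axis) of list members detected in both pools, red bars are list medians, and grey bands hold the central 95% of medians of random lists matched on signal. The medians of the profibrotic list (0.22) and the miR-23/27/24 clusters (0.29) lie above their bands and that of the GC-rich list (−0.15) lies below its band. Against random lists matched on probe GC content as well, all of these medians lie inside the central 95%.

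Markers of other cell types were mostly not detected. None of 15 epithelial, 2 endothelial, or 11 muscle, liver and neural miRNAs was detected in either pool. Of 13 blood cell miRNAs 4 were detected, with a median of −0.25 (percentile 3.42): miR-16-5p, the red cell miRNA miR-451a (−0.19 ± 0.25), miR-155-5p (−0.38 ± 0.31) and miR-342-3p (0.03 ± 0.16). Several of these are also expressed outside blood. Of 8 miRNAs often seen in bovine serum, which was in the growth medium before the serum-free step, 6 were detected, with a median of −0.18 (percentile 3.49). This list shares miR-16-5p and miR-451a with the blood list, and also held miR-92a-3p, miR-320a (0.21 ± 0.10) and miR-1246. Its highest ratio, named after its value was seen, was that of miR-423-5p (0.26 ± 0.25). Of 17 sequences annotated as miRNAs but possibly fragments of other small RNAs, 12 were detected in both pools and 1 in non-IPF only. Of the 12, miR-1246 and miR-1290 were at least 2-fold lower, and the median was 0.04 (percentile 75.8). It was −0.03 with median scaling, which shifted every ratio by −0.06. All 38 GC-rich miRNAs that are often bright on this kind of array were detected. Their median of −0.15 lay at percentile 0.66 and was 0 with quantile normalization, with miR-1268a at −0.86 ± 0.05, miR-6089 at −0.25 ± 0.05 and miR-5787 at 0.44 ± 0.05. Against other miRNAs matched on probe GC content as well as signal, this list was at percentile 22.97, the profibrotic list at 95.3, the miR-23/27/24 clusters at 95.5 and the bovine serum list at 2.34, the only 1 of the 12 lists outside the central 95% of its matched lists. With a list's own members among the miRNAs drawn and no miRNA drawn more than once per list, the bovine serum list was at percentile 2.94, inside that range.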

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

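The test of a gain common to all spots, that of labelled RNA and that of a damaged patch were chosen after the result was seen. Control probes carried on the arrays for other purposes were far above the negative controls, which averaged 3.43 ± 3.35 (SD over 1000 spots) on the IPF array and 3.21 ± 3.11 on the non-IPF array. What these control probes target is not stated in the files. Their unscaled signals in IPF and non-IPF were 110676 and 119295 for hur_1, 10229 and 15824 for hur_2, 679 and 741 for hur_4, 58.6 and 70.7 for hur_5, 909 and 851 for hur_6, and 1495 and 2308 for mr_1. On the scaled log2 scale, hur_2 stood at −1.15 and mr_1 at −1.15, within the range of the 8 miRNAs counted as lower in IPF, and hur_1 at −0.63, hur_4 at −0.65, hur_5 at −0.79 and hur_6 at −0.43, outside it.

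Before scaling, 415 of 438 miRNAs had higher signal on the IPF array, with a median log2 ratio of 0.54. A gain common to every spot of that array would have lifted the 6 bright control probes too, and their median unscaled log2 ratio was −0.20 (SD 0.30, from −0.63 to 0.09). This would argue against such a gain only if these controls bound equal amounts of target on both arrays. Their targets are not stated and their ratios were spread, so the controls cannot decide it. More labelled small RNA from the IPF pool, whether from loading, from the make-up of the vesicle RNA or from disease, stays open. The spike-in probes that might decide this were well above background in 0% of spots on both arrays. The equal RNA input of 20 ng does not settle it, since the miRNA share of that RNA was not measured.

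The 8 miRNAs at least 2-fold lower on the IPF array had a median ratio of −1.25. After a straight line on probe GC content was removed, their median residual was −1.30, which argues only against a straight trend with GC content. The 9 other detected probes of 7 of these miRNAs had a median of −1.16, which argues against faults of single probes. Those probes target the same miRNAs, so they cannot exclude a cause in the shared sequence. With the array divided by rows and columns into 4 parts, and 6 to 8 of the 8 miRNAs measured in each part, the median was between −1.29 and −1.22, which argues against a damaged patch. CA repeats stay open: 5 of the 8 carry CACACA or ACACAC in the probe, and the 3 other detected miRNAs with such a probe had a median of −0.09, from −0.14 to 0.46, a set that leaves out the lower miRNAs by its construction and so decides nothing, while all 8 detected miRNAs with such a probe had a median of −1.21, 5 of them being the miRNAs in which the repeat was noticed. A difference between IPF and non-IPF vesicles also stays open, as a hypothesis that 1 pool per group cannot test.

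The miR-23/27/24 clusters lay above random lists matched on signal (percentile 99.1) and the GC-rich list below them (percentile 0.66). Across all 438 miRNAs the ratio went down by about 0.03 per 10% of probe GC content. Against other miRNAs matched on signal and GC content, the GC-rich list was at percentile 22.97, as a GC trend of the arrays would give. The miR-23/27/24 clusters were at percentile 95.47, between the ranges set in advance for and against GC content as the cause. They were at 93.12, within the range set for it, in a first draw that included their own members and drew no miRNA more than once per list. These percentiles therefore cannot tell GC content apart from another cause for these 5 miRNAs. The clusters' median ratio was 0.29 in each comparison, at a median probe GC content of 50%. With GC matching, the upper end of the central 95% of random lists went from 0.27 to 0.31. A slope of about 0.03 per 10% is small beside 0.29. This argues against a straight GC trend as the source of most of that ratio for these 5 miRNAs. A difference between the vesicle pools remains untested there. The clusters also hold miR-23b-3p, which the study is recalled to have followed up, so their position is not independent evidence.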

How the results depend on the processing

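The fold threshold of 1.5 and the GC-matched random lists were added after the data were seen. No paired analysis was possible because each group had 1 array and the result comes from no test; for the same reason no replicate could be left out. Of 217 alternative values of the main results, 174 were the same within 1.5-fold (counts) or within the spot SD (ratios), and 43 were labelled moved. The alternative shares of the 10 brightest miRNAs were labelled moved without such a rule. Detection of a probe does not use the scaling, which enters only through the choice of the probe that represents a miRNA. Without scaling, 7 rather than 8 miRNAs were detected in non-IPF only. The gene detection flag keeps each miRNA's ratio. Some values in this tally and the next could therefore hardly have moved, and the tallies are no measure of robustness. Of 484 alternative values of other named miRNAs, 363 stayed within the spot SD, 121 moved and 443 kept their sign; the 8 lower miRNAs kept theirs under all 11 settings. The lowest signals of detected miRNA probes were 19.3 in IPF and 17.2 in non-IPF, against negative controls that averaged 3.43 and 3.21. Without scaling, which by construction adds the same amount to all ratios (0.52 in the median), 8 miRNAs were at least 2-fold higher and 0 lower, miR-23b-3p was at 0.97 and miR-494-3p at 1.003. List medians were then 0.61 (antifibrotic), 0.74 (profibrotic), 0.63 (fibroblast), 0.48 (let-7), 0.64 (14q32), 0.81 (miR-23/27/24), 0.51 (miR-17/92), 0.63 (senescence), 0.27 (blood), 0.34 (bovine serum), 0.56 (fragments) and 0.37 (GC-rich). With normexp, which shifted the median of all miRNAs by −0.13, 2 miRNAs were lower, miR-23b-3p was at 0.13 and miR-494-3p at 0.36, and medians were 0.048 (profibrotic), −0.12 (14q32), 0.15 (miR-23/27/24), 0.15 (fragments) and −0.054 (GC-rich). Its offset of 50 was added to both arrays before scaling, which by construction draws unscaled ratios of dim miRNAs toward 0. Scaling came afterwards, so scaled ratios of dim miRNAs need not move toward 0, and the antifibrotic median went from 0.09 to −0.03. The offset was not separated from the background correction, so changes under normexp may come from either. Total gene signal gave 11 higher and 14 lower, and the deposited values gave 13 higher and 14 lower; of those higher, 0 were detected in both pools by the spot rule, and their highest IPF signal was 34.3. Those settings and the gene detection flag, which call more dim miRNAs, each gave 19 miRNAs detected in non-IPF only. The brighter part of the miRNAs held 5 lower ones, by its construction. At 1.5-fold, 2 were higher and 20 lower. Other values that moved were, without the GC-rich miRNAs in the scaling, 0.58 (miR-494-3p), 0.13 (fragments) and −0.053 (GC-rich list); with median scaling, −0.025 (fragments) and −0.21 (GC-rich); with quantile normalization, 0 (GC-rich); and with the deposited values, 0.25 (fibroblast). From total gene signal the 10 brightest miRNAs held 72.5% in IPF and 70.1% in non-IPF. Leaving the GC-rich miRNAs out of the scaling shifted every ratio by 0.09, and median scaling by −0.06, which by construction gives the values listed for those settings. For the values from quantile normalization, the deposited values and total gene signal the cause was not tested.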

Other observations

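The tests of shared genomic loci and of CA repeats had their bounds set before their results were seen. The 2 miRNAs at least 1.5-fold higher in IPF vesicles, named after their values were seen, were miR-4291 (0.81 ± 0.23, unscaled signals of 50.6 and 20.1) and miR-6790-5p (0.59 ± 0.18, 49.6 and 22.99). Both were dim. Ratios of miRNAs made from one precursor or neighbouring precursors were as follows: miR-221-3p was at 0.05 and miR-222-3p at 0.04, miR-25-3p at 0.07 and miR-106b-5p at −0.01, miR-30b-5p at 0.06 and miR-30d-5p at 0.19, and miR-23b-3p at 0.45 and miR-27b-3p at 0.29. Further pairs were miR-23a-3p at 0.10 and miR-27a-3p at 0.23, miR-99a-5p at 0.01 and let-7c-5p at −0.14, miR-31-5p at −0.07 and miR-31-3p at 0.13, and miR-939-5p at 0.16 and miR-1234-3p at −0.13. The arms of miR-193b were at 0.15 (5p) and 0.47 (3p).

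A hypothesis that miRNAs of one locus share their ratio was tested on 9 pairs with probes up to 10 kb apart on hg19. The median absolute difference within pairs was 0.15, against a median of 0.23 for random pairs matched on signal (0.098 to 0.44 for the central 95%), which is percentile 15.39. The bound set in advance read any percentile of 5 or more as evidence against sharing. That bound was too loose for 9 pairs, since the random range is wide enough to hold pairs that do share their ratio, so the question stays open.

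The probes of miR-1246 (CCTGCTCCAAAAATCC) and miR-1290 (TCCCTGATCCAAAAATCC) end in the same bases, CCAAAAATCC, and had ratios of −1.31 and −1.39. Of the other lower miRNAs, the probe of miR-4455 is AAAAACACACACACCC (−1.27), that of miR-574-5p ACACACTCACACACACAC (−1.22), that of miR-3149 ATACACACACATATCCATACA (−1.21), that of miR-32-3p AAATATCACACACACTAAATTG (−1.31) and that of miR-595 AGACACACCACGGCACA (−1.21). RNA with GU repeats could bind these probes, and a lower amount of it on the IPF array might then lower unrelated miRNAs together. The probes of let-7b-5p (AACCACACAACCTACTACC), miR-1299 (TCCCTCACACAGAATTC) and miR-6849-5p (TCCACACACTCCCCT) also hold CACACA or ACACAC and were at −0.09, 0.46 and −0.14, with a median of −0.09351. That median leaves out the CA-repeat miRNAs that were 2-fold lower, so it leans toward 0 and decides nothing. Over all 8 detected miRNAs with such a probe the median was −1.21, against 0.02 for those without, but the repeat was noticed in the lower miRNAs themselves, so the hypothesis stays undecided.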
